A study of Mus musculus with 6 samples.

How the data were processed

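RNA from 6 mouse livers was measured on Agilent single-colour arrays. Per the file headers, each array was read by Agilent Feature Extraction 10.7.3.1 with the protocol GE1_105_Dec08 and a probe design annotated on mm9; the submitters' processing notes name Feature Extraction 10.5. Each deposited scanner file holds the processed intensity of every spot, background-subtracted and floored above 0 by the software per the file headers, and not normalized between arrays. The authors' deposited series table holds log2 values, 1 per probe, with array medians of 6.46 to 6.48; the values correlated with the log2 median signal of the same arrays at r = 0.996 to 0.999, and how the arrays were equalised is not given in the sources used here. NTBC was given in drinking water per the labels.

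Control spots and spots marked as outliers were left out, as were 29 probes then missing on an array, and spots of a probe were averaged. No spot was saturated. The values tested were log2 of the processed signal minus the array's 75th percentile. The files carry no gene names: accessions were matched without versions to a RefSeq table of GRCm38.p6, used only for names and neighbours since the array design is on mm9. Of 41174 probes 26933 were named and 14241 were left unnamed. They stood for 18353 genes, 6540 of them with more than 1 probe, and the probe with the highest mean over the 6 arrays was used. In the comparison of tumour with inflamed FCR liver, 5535 genes had several measured probes, whose log2 differences had a median range of 0.535; for 1184 genes they differed by more than 1.

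Genes well above background on at least 2 arrays of a fit were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment at 0.05. A model of 4 group means over all 6 arrays, with 2 residual degrees of freedom, gave tumour against inflamed FCR liver, both withdrawal comparisons and their difference; lone arrays were assumed to vary like the other groups. The comparison named by the series' design text used its 4 arrays only. Replicate numbers follow sample order; in the tumour and inflamed groups they coincide with regimen and slide, and arrays were matched across groups only in the fits with slide or regimen as a block. Fah and FCR liver on continuous NTBC, 1 array each, were compared by size, with lists set against 10000 random lists of the same size matched on mean expression.

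The 30 gene lists, the groups, the tests, the rule for named genes and most alternatives were fixed before the data were examined. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, with an estimated correlation, fry and fgsea 1.28.0 as alternatives. Some genes stand in several lists, so list results are not independent of each other. Genes named in the first 2 comparisons are the 10 largest rises and falls that passed, had groups that did not overlap and lay well above background on every array of the higher group, filled up to 5 with changes at an unadjusted p under 0.05 where fewer qualified, and 5 each way in the others. Up to 4 members per list with the largest change were added, and 5 each way on continuous NTBC. Fah, Rag2, Il2rg and Afp were followed in every array, and genes named in one comparison could be followed through the others; which ones were followed was decided after values were seen. Some genes that the rule names are not reported here.

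Alternatives were normexp background correction with an offset of 50, quantile normalization, the array median in place of the 75th percentile, no filter and a stricter filter on dim probes, slide as a block, the mean of a gene's probes, eBayes without a trend, the authors' values, leaving out each array of a pair, other choices of FCR arrays and regimen as a block. Normexp used the median spot signal because the files hold no mean signal. Values floored at a common level of -5.12 and a test of every probe on its own were chosen after seeing the data.

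The steps were tested on simulated data with 200 changed genes in each of 5 draws. Genes changed by 4 on the log2 scale were recovered at 28% among 15175 genes for the comparison of the design text. Among 15381 genes the share was 75.5% for tumour against inflamed FCR liver, 29% and 38% for the Fah and FCR withdrawal comparisons, and 0% for their difference, where changes of 6 were recovered at 8.5%. False calls were 4.45% to 6.80% of all calls. A list of 20 genes raised by 1 was found by camera with the preset correlation in 5 of 5 draws in 4 comparisons and in 3 of 5 for the difference, and in 0 of 5 with an estimated correlation in each. Simulated genes varied independently, with a spread drawn from the fitted model. The draws therefore cannot tell whether the preset correlation holds for real lists, whose genes may vary together.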

Results

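Gene expression was measured in 6 mouse liver samples, each on 1 single-colour array of mouse probes. The mice lacked Fah, fumarylacetoacetate hydrolase, the last enzyme of tyrosine breakdown. The drug NTBC blocks an earlier step of that pathway and keeps such mice healthy, so that its withdrawal injures the liver. The second strain, FCR, lacked in addition Rag2, which is needed to assemble antigen receptors, and Il2rg, the common gamma chain of several cytokine receptors. Such mice have no mature T and B cells and no NK cells. By their labels, the samples were healthy liver of a Fah mouse (n = 1), tumour from Fah mice (n = 2), normal liver of an FCR mouse (n = 1) and inflamed liver of FCR mice (n = 2). Healthy and normal liver came from continuous NTBC. In the tumour and in the inflamed group, replicate 1 had the regimen labelled off and replicate 2 the regimen labelled 2xoff/on; the labels leave open in which phase of NTBC each liver was taken.

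Slide 1 held the 4 arrays of continuous NTBC and of off, and slide 2 held both 2xoff/on arrays, so that regimen and slide change together within a group. Each array gave 43379 spots, of which 60.5% to 74.5% were well above background. The 75th percentile of the processed signal was 363 on the healthy array, 811 and 890 on the tumour arrays, 374 on the normal FCR array, and 363 and 722 on the inflamed FCR arrays. Nothing in the labels says that the arrays of a group came from separate animals. The p-values of single genes measure only the spread between these samples, which here includes regimen and slide. Those of camera with the preset correlation set a list's genes against the other genes and treat genes as nearly independent. A very small camera p therefore does not measure how far livers vary. The number of arrays limits the precision. In a principal component analysis the first component (54.1% of the variance) parted the healthy and normal arrays from the other 4. The second (21.8%) set inflamed FCR replicate 1, at 104.3, apart from the other arrays, which lay between -53.02 and 7.96.

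The targeted genes were looked at first, as log2 signal relative to the array's 75th percentile. Il2rg was well above background on the 3 Fah arrays, at -3.40 in healthy liver and at -1.94 and -1.98 in tumour, and on none of the 3 FCR arrays, where it lay between -7.74 and -6.70. Rag2 was not well above background on any array. Fah gave signal on all 6 arrays, from -2.85 to -0.97; where its probe lies relative to the deleted part is not known, so this value checks nothing. Afp, the fetal alpha-fetoprotein often found in liver tumours, was at 1.81 in healthy Fah liver and 2.46 in normal FCR liver. It reached 7.85 and 8.37 in the tumours and 9.24 and 8.23 in inflamed FCR liver. The Y-linked genes Ddx3y and Eif2s3y were well above background on all 6 arrays, with lowest values of 1.08 and 1.88.

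Fah tumour was compared with inflamed FCR liver at the same NTBC regimens. The Fah arrays here were labelled tumour and the FCR arrays inflamed liver. Effects of lymphocytes, of genotype and of tumour tissue therefore cannot be told apart. Cpa3, a mast cell carboxypeptidase, was 6.72 ± 0.83 (log2 difference ± SE, n = 2 and 2) higher in tumour (limma, adjusted p = 0.0255), and Mcpt4, a mast cell protease, 6.10 ± 0.89 higher (adjusted p = 0.0427). Jchain, the joining chain of IgA and IgM, rose by 6.27 ± 0.61 (adjusted p = 0.0115). In the other direction, Ifi202b, an interferon-inducible gene, was at least 120-fold lower in tumour (adjusted p = 0.0029), Lypd6b at least 221-fold, the keratin Krt76 at least 92.1-fold and Wdr64 at least 53.1-fold. Where a gene was well above background on no array of a group, its level there is only a bound. Such a fold sets the brighter group's mean against, for each dim array, the higher of the gene's own value and the lowest value of any probe well above background.

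Changes are read relative to the median of all tested genes, which was -0.13 here, -0.15 in the comparison named by the design text, -0.08 and 0.04 in the Fah and FCR withdrawal comparisons and -0.06 in their difference. In all, 10 genes rose and 22 fell among 15381 tested (limma, Benjamini-Hochberg), against 1412 at an unadjusted p under 0.05. With regimen as a block over all 6 arrays, a fit that also takes in the continuous NTBC pair, 45 genes passed, 11 of them among these 32. Of the 49 genes named in this comparison, 13 no longer passed in that fit, among them Cpa3 (adjusted p = 0.232), Mcpt4 (0.212), Jchain (0.0644), Lypd6b (0.276), Krt76 (0.282) and Wdr64 (0.304). The others were Cldn7 (0.244), Slc1a2 (0.127), Krt5 (0.224), Mup5 (0.282), Mup6 (0.256), Meig1 (0.275) and Cyp4a12a (0.155). In the same fit 7 newly passed: Ltb (0.00881), Ms4a1, Cd74, Isg15 and Ifi44 (all 0.0194), and Cd8a and H2-Ab1 (both 0.0477). Il2rg rose by at least 13.2-fold and Rab6b, a small GTPase of vesicle transport, by at least 30.4-fold. Cldn7, an epithelial tight junction protein, rose by 3.92 ± 0.51, Zfp874a by 5.47 ± 0.56, and Zc3h12d by 4.20 ± 0.62. Slc1a2, a glutamate transporter of pericentral hepatocytes, rose by 3.71 ± 0.49, and its 4 probes ranged from 2.16 to 4.93. Krt5, a basal keratin, differed by -4.98 ± 0.54, Dct, a melanin enzyme, by -5.76 ± 0.58, and the major urinary proteins Mup5 and Mup6 by -4.97 ± 0.51 and -5.58 ± 0.77. Gdpd3 differed by -5.15 ± 0.64 and Meig1, well above background on 1 of 2 tumour arrays, by -5.81 ± 0.84. Afp differed by -0.62 ± 0.50, within the spread (adjusted p = 0.795).

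The lymphocyte lists lay higher in tumour as groups. Of 16 measured B cell and plasma cell markers, 1 rose (7 adjusted over the list alone) and 15 did not pass, with a median difference of 1.66 (camera, adjusted p = 7.17e-09). The T cell list had no member that passed (6 of 17 adjusted over the list alone), a median of 0.83 and a camera adjusted p of 1.56e-07. Cd8a, a receptor of cytotoxic T cells, was at least 7.55-fold higher without passing, and Cd3e, of the T cell receptor complex, differed by -0.33 ± 0.57. Cd3e was well above background on both inflamed FCR arrays, with a mean of -1.12 against -1.45 in tumour. Its signal in FCR mice, which have no mature T cells, is not explained here. The NK and cytotoxic list had a median of 1.88 (adjusted p = 1.82e-06), with 5 of 14 members higher and 1 lower adjusted over the list alone; with floored values the median was 0.64 (adjusted p = 0.00192). Gzma, a granzyme, was at least 4.96-fold higher without passing, while Nkg7, a granule protein, differed by 3.54 ± 0.66 and Eomes, a transcription factor of NK and T cells, by -4.31 ± 0.81. With an estimated correlation camera passed none of these lists: adjusted p = 0.401 for the T and B cell lists and adjusted p = 0.407 for the NK list. In the simulated data that form found a raised list in 0 of 5 draws in each comparison. Not passing it is therefore little evidence against a list, here and below. On continuous NTBC the T, B and NK lists had Fah minus FCR medians of 0.25, 1.07 and 1.51, over 14, 13 and 7 members. Their withdrawal responses did not pass as different between genotypes (camera, adjusted p = 0.118, 0.128 and 0.238). Among further genes short of the threshold without the regimen block, Ms4a1, the B cell antigen CD20, was at least 6.96-fold higher, and the MHC class II genes Cd74 and H2-Ab1 differed by 2.63 ± 0.46 and 2.34 ± 0.45, and Ltb, lymphotoxin beta, by 3.50 ± 0.63.

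Lists of injury and metabolism lay apart too. All 24 measured NRF2 targets, genes of the antioxidant response, lay lower in tumour, with a median of -1.62 (camera, adjusted p = 3.54e-19), and none passed over all genes while 18 did adjusted over the list alone. The glutathione transferases Gsta2 and Gsta1 differed by -3.03 ± 0.48 and -2.69 ± 0.49, G6pdx, which makes NADPH, by -2.87 ± 0.47, and Slc7a11, a cystine transporter, by -3.44 ± 0.81. The type I interferon list was lower, with a median of -1.28 (adjusted p = 1.07e-08; 0 of 18 passed, 6 adjusted over the list alone); Isg15 differed by -2.75 ± 0.53, Ifi44 by -2.67 ± 0.55 and Rsad2 by -2.55 ± 0.58. On continuous NTBC the interferon list had a Fah minus FCR median of -1.32, and its withdrawal response did not pass as different between genotypes (median 0.01, adjusted p = 0.668). Cell cycle genes were higher (median 1.41, adjusted p = 2.17e-14; 0 of 30 passed), with Cdkn3 at 2.91 ± 0.76 and Top2a at 3.13 ± 0.98. Wnt targets and pericentral genes were higher (median 0.80, adjusted p = 1.56e-07), all 16 positive and 1, Slc1a2, passing. With regimen as a block Slc1a2 did not pass (limma, adjusted p = 0.127). Oat differed by 2.77 ± 0.50 and Lgr5 by 1.67 ± 0.59. PPAR-alpha targets were lower (median -0.99, adjusted p = 3.40e-06), and 1 of 21, the fatty acid hydroxylase Cyp4a12a, fell by 3.33 ± 0.49, while Cyp4a10 differed by -2.84 ± 0.62. Cyp4a12a is also in the male-biased list, and with regimen as a block it did not pass (limma, adjusted p = 0.155). With an estimated correlation camera passed none of these lists: adjusted p = 0.401 for NRF2, Wnt and PPAR-alpha targets, and adjusted p = 0.407 for the interferon and cell cycle lists.

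The other lists called by camera were matrix genes (median 1.07, adjusted p = 1.08e-07, Col1a2 1.79 ± 0.48), oncofetal genes (1.04, 1.71e-04, Dlk1 3.90 ± 0.92), macrophage markers (0.31, 0.00212), the unfolded protein list (-0.47, 0.00179, Fgf21 -2.85 ± 0.62 and Asns -2.24 ± 0.51), p53 targets (-0.70, 0.00235), cytochrome P450 enzymes (-0.63, 0.00235) and male-biased liver genes (-0.62, 0.00235). Their values were adjusted p = 0.407 to adjusted p = 0.618 with an estimated correlation. The remaining 15 lists did not pass. Their adjusted p was 0.0564 for erythroid markers, 0.0573 for bile acid genes, 0.411 for female-biased genes, 0.527 for immediate early genes, 0.811 for gluconeogenesis, 0.853 for tyrosine catabolism and exocrine pancreas, 0.877 for hepatocyte secreted genes, 0.929 for antigen presentation and the acute phase, 0.944 for lymphotoxin and chemokines, 0.946 for the urea cycle, 0.95 for neutrophils, 0.966 for endothelium and 0.979 for lipogenesis. Lipogenesis had opposite medians on slide 1 and slide 2, 1.49 and -1.46. Median, mean and test differed in sign for the neutrophil (0.46, -0.18, down), tyrosine (-0.02, 0.04, up) and endothelial (0.20, -0.14, up) lists, and the test alone was up for the urea cycle, lipogenesis and acute phase lists, whose medians were -0.02, -0.03 and -0.16; antigen presentation had a median of -0.27 and a mean of 0.00. Among members of lists that did not pass, Il6 differed by -3.63 ± 0.58, the prostaglandin synthase Ptgs2, well above background on 1 of 2 tumour arrays, by -5.82 ± 1.09 and the lymphatic and sinusoidal receptor Lyve1 by -3.60 ± 0.64.

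The test fry asks whether a list's genes move on balance one way, and in a second form whether they change in either direction; neither form compares a list with other genes. It passed 0 of 30 lists one way (8 at an unadjusted p under 0.05) and 9 in either direction, the T, B and NK lists among them at an adjusted p of 0.0257. Within slide 1 and slide 2 the NRF2 list had medians of -1.88 and -1.61 and the B cell list 1.41 and 1.85. The macrophage list turned, with -0.69 and 1.5, the matrix list had 0.45 and 1.12, the p53 list -1.25 and -0.23 and the P450 list -0.30 and -0.79. With slide as a block 984 genes passed (524 higher), but that fit keeps 1 residual degree of freedom and rests on the spread shared by all genes. Leaving out 1 array at a time, which leaves a lone array assumed to vary like the other groups, gave 61 genes without tumour replicate 1, 59 without tumour replicate 2, 56 without inflamed FCR replicate 1 and 799 without inflamed FCR replicate 2. Other settings gave from 0 genes (values floored at a common level) to 190 (normexp).

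**Figure D1:**
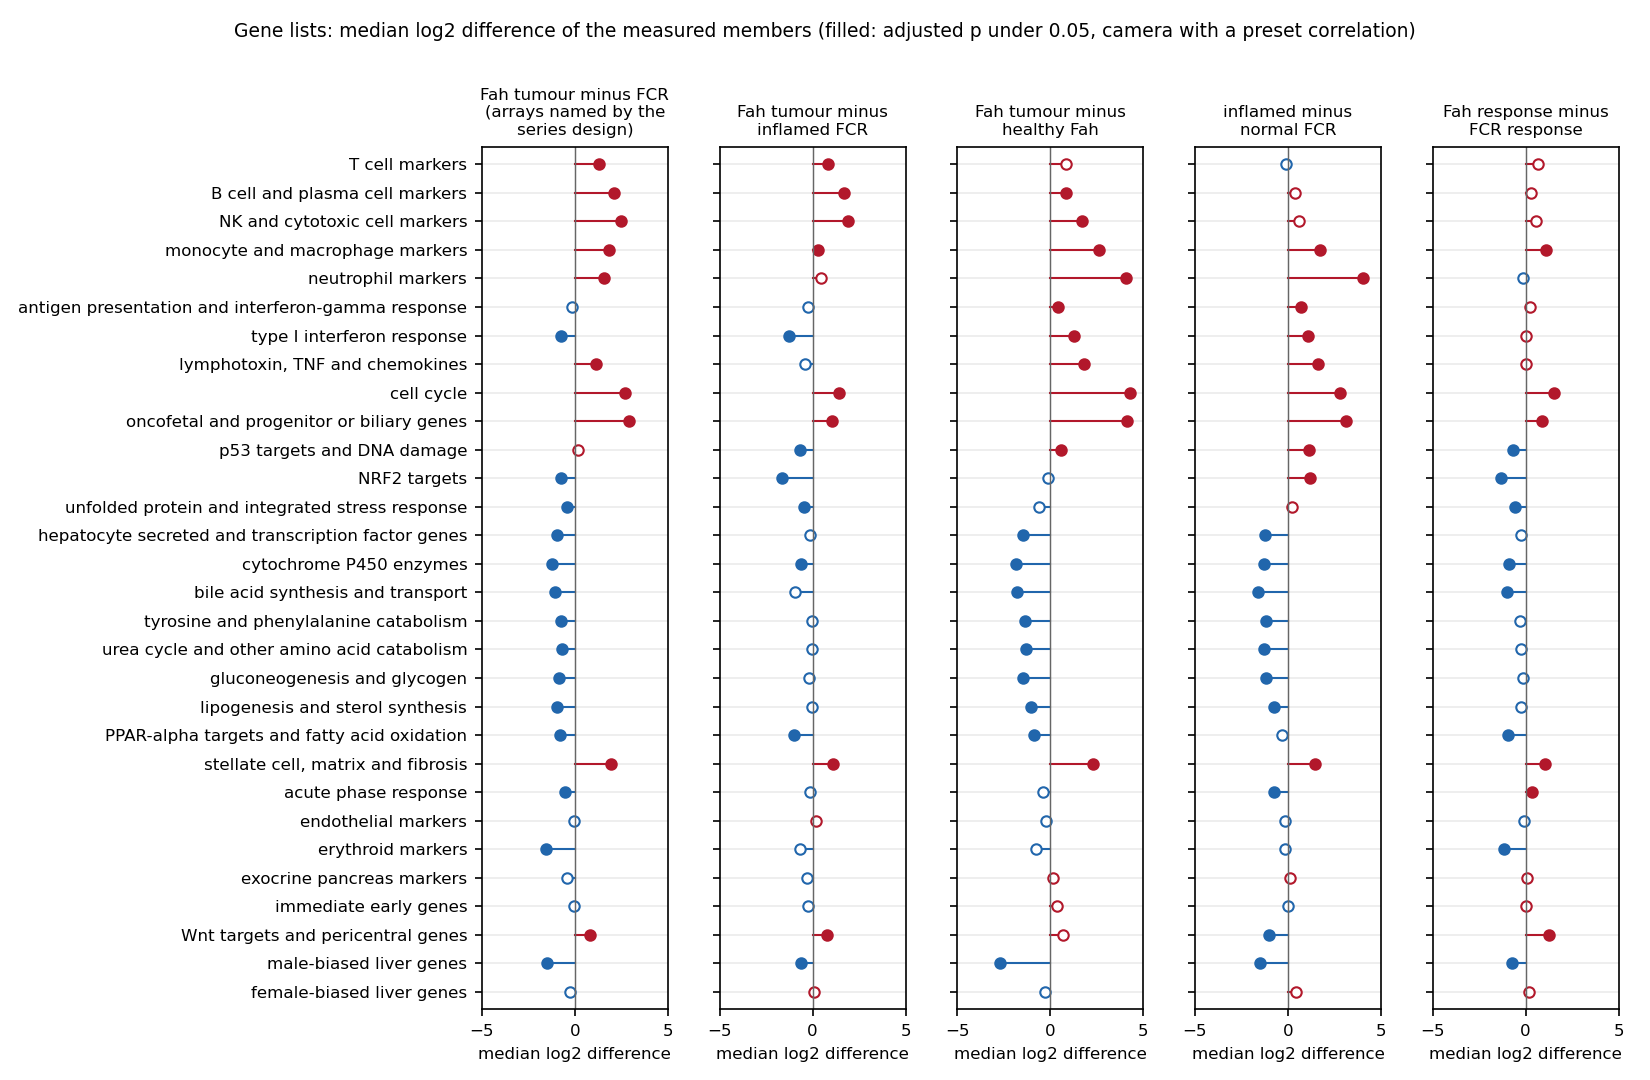
Median log2 difference of the measured members of each of the 30 gene lists (vertical axis) in the 5 tested comparisons (panels; horizontal axis, log2 difference). Red points lie above 0 and blue points below, and filled points passed camera with a preset correlation; in Fah tumour against inflamed FCR liver the NRF2 list lay at -1.62 and the B cell list at 1.66.

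**Figure D2:**
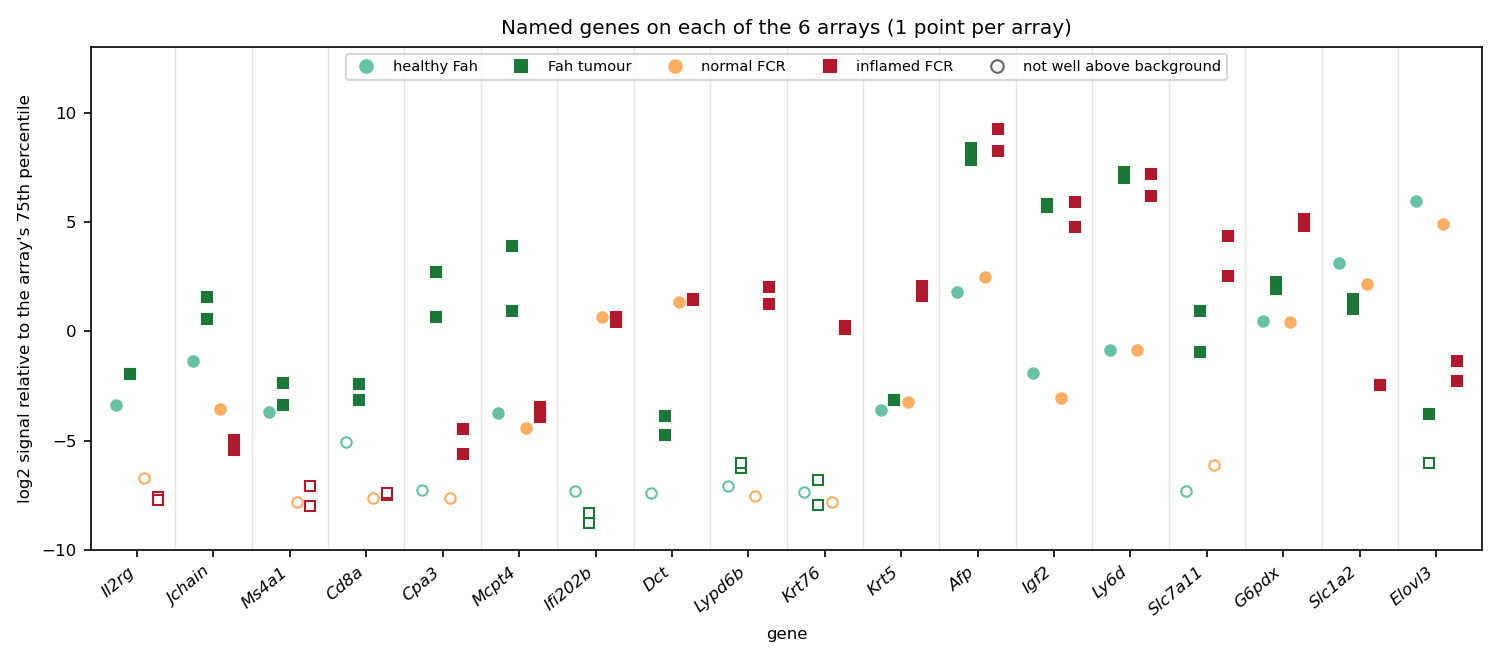
Signal of 18 named genes on the 6 arrays, 1 point per array, as log2 relative to the array's 75th percentile; open symbols were not well above background. Il2rg was well above background on the 3 Fah arrays only, and Krt76 and Lypd6b on the inflamed FCR arrays only.

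The design text names a comparison of both tumour arrays with the normal FCR array and inflamed FCR replicate 2, for gene set enrichment in hepatic Fah cells against FCR; its gene sets are not used here. The FCR side of this comparison joins continuous and cycled NTBC. Markers of T, B and NK cells, macrophages and neutrophils lay higher in tumour: the median was 1.29 for T cells (camera, adjusted p = 2.41e-06; 6 of 17 adjusted over the list alone), 2.11 for B cells (2.63e-09; 9 of 15), 2.50 for NK cells (6.03e-09; 9 of 14), 1.83 for macrophages (9.06e-12; 9 of 22) and 1.57 for neutrophils (0.00447; 0 of 15). The matrix list was higher by a median of 1.96 (8.56e-15; 12 of 24), the cell cycle list by 2.70 (4.31e-12; 0 of 30), the oncofetal list by 2.88 (1.05e-09; 5 of 20), the lymphotoxin and chemokine list by 1.13 (5.15e-05; 2 of 26) and the Wnt list by 0.80 (0.0114; 0 of 16). With an estimated correlation these gave adjusted p = 0.388 for the T, B, NK, macrophage and matrix lists, adjusted p = 0.451 for the cell cycle, oncofetal, chemokine and Wnt lists, and adjusted p = 0.541 for neutrophils. With floored values the neutrophil list did not pass (adjusted p = 0.0548), and the T and NK cell medians were 0.81 and 1.33.

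No single gene passed in that comparison: limma called 0 of 15175 genes, against 1751 at an unadjusted p under 0.05 (1171 higher), and the smallest adjusted p was 0.115, for Ifi202b. The differences given here are therefore values only. Mcpt4 differed by 6.34 ± 1.03. Well above background on 1 of 2 FCR arrays, Cpa3 differed by 7.73 ± 1.23, Wnt10a, a Wnt ligand, by 6.66 ± 1.12, and Gpnmb, a glycoprotein of lipid-laden macrophages, by 5.66 ± 1.65; part of each value rests on a signal near background. Rab6b was at least 28.4-fold higher and Ifi202b at least 128-fold lower. Il2rg was at least 12.3-fold higher and Afp differed by 2.77 (adjusted p = 0.296 and 0.641). The Afp value rests on the normal FCR array: it was -0.12 without that array and -0.62 against both inflamed FCR arrays. Jchain differed by 5.33 ± 0.69, Ltb by 5.49 ± 0.88, Lck, a T cell kinase, by 3.14 ± 0.66, Nkg7 by 3.51 ± 0.62, Trem2, a macrophage receptor, by 3.48 ± 0.73, Cd74 by 3.32 ± 0.64 and H2-Ab1 by 3.09 ± 0.56. Not well above background on either FCR array, Cd8a was at least 7.05-fold, Ms4a1 at least 6.50-fold and Gzma at least 4.63-fold higher. Of the matrix genes, Col1a1 differed by 3.84 ± 0.67, Col3a1 by 3.28 ± 0.51 and, measured on 1 of 2 FCR arrays, the elastase Mmp12 by 4.14 ± 0.66. Top2a differed by 3.56 ± 1.35, Epcam by 4.32 ± 1.04 and Dlk1, also measured on 1 of 2 FCR arrays, by 4.57 ± 1.40.

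Lists of liver function and some others lay lower in the same comparison. The median was -1.24 for cytochrome P450 enzymes (camera, adjusted p = 1.93e-07), -0.98 for hepatocyte secreted genes (4.74e-07), -0.97 for lipogenesis (9.55e-07), -1.47 for male-biased genes (3.48e-05), -0.79 for PPAR-alpha targets (4.79e-05), -0.69 for the urea cycle list (2.66e-04), -0.74 for NRF2 targets (3.00e-04), -1.09 for bile acid genes (3.67e-04), -0.73 for type I interferon (0.00113), -0.87 for gluconeogenesis (0.00146), -0.52 for the acute phase (0.00209), -0.74 for tyrosine catabolism (0.00697), -1.54 for erythroid markers (0.0335) and -0.45 for the unfolded protein list (0.0483). They gave adjusted p = 0.388 to adjusted p = 0.535 with an estimated correlation, and with floored values the erythroid and unfolded protein lists did not pass (adjusted p = 0.0692 and 0.0548). Cyp2c54 differed by -4.19 ± 1.23, Cyp2f2 by -3.27 ± 0.52, Cyp8b1, of cholic acid synthesis, by -3.64 ± 0.68, the lipogenic regulator Thrsp by -4.35 ± 0.60, and Scd1, a fatty acid desaturase, by -2.06 ± 0.53. The urinary proteins Mup5 and Mup6 differed by -6.78 ± 0.85 and -6.65 ± 1.30, the fatty acid elongase Elovl3, measured on 1 of 2 tumour arrays, by -6.20 ± 2.31 and Dct by -5.70 ± 0.53. The p53, exocrine pancreas, antigen presentation, endothelial, immediate early and female-biased lists did not pass (adjusted p = 0.584, 0.694, 0.894, 0.723, 0.894 and 0.945). Of these, the antigen presentation, endothelial, immediate early and female-biased lists had medians of -0.17, -0.04, -0.04 and -0.25 with means or tests of other sign. Within slides the neutrophil list had medians of 3.17 and 0.05, the oncofetal list 4.85 and 0.93, the cell cycle list 4.03 and 1.24, the interferon list 0.02 and -1.48 and the NRF2 list -0.29 and -1.61, while the B cell list had 2.13 and 2.01 and the Wnt list 0.14 and 0.95. With slide as a block 51 genes passed and the unfolded protein list did not (adjusted p = 0.0911); 68 genes passed without normal FCR replicate 1 and 2265 without inflamed FCR replicate 2, and 35 with the FCR side replaced by both inflamed arrays.

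Fah tumour was set against healthy Fah liver to describe the response to NTBC withdrawal and tumour growth in mice with lymphocytes. Proliferation and fetal liver genes rose: 22 of 30 cell cycle genes (25 adjusted over the list alone) and 16 of 20 oncofetal genes (20). Igf2, a fetal growth factor, rose by 7.67 ± 0.65 (n = 2 and 1; limma, adjusted p = 0.00308), Gpc3, a fetal glypican, by 6.72 ± 0.61, Dlk1 by at least 81.1-fold, Ly6d by 8.04 ± 0.62 and Afp by 6.30 ± 0.62. Cdkn3 rose by 6.38 ± 0.93, Ccnb1, a mitotic cyclin, by 5.65 ± 0.71 and Tpx2, a spindle protein, by 5.50 ± 0.82. The camera test gave the cell cycle list a median of 4.28 (adjusted p = 9.50e-24) and the oncofetal list 4.15 (adjusted p = 1.20e-21), with adjusted p = 0.319 for both with an estimated correlation.

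In all, 604 genes rose and 174 fell in tumour among 15381. Among the rises were those of Gpnmb (at least 160-fold), Cpa3 (at least 111-fold), Tmem54 (at least 110-fold), Krt20 (at least 96.1-fold) and Ly6d. Mcpt4 rose by 6.12 ± 1.09, Slc7a11 by at least 34.3-fold, and Syt13 by at least 15.9-fold. Of 22 macrophage markers 5 rose (13 adjusted over the list alone; median 2.60, adjusted p = 7.14e-09), with Trem2 at 6.10 ± 1.19. Of 15 neutrophil markers 5 rose (11; median 4.08, adjusted p = 3.54e-08), among them S100a8 by 5.27 ± 0.97 and Camp, an antimicrobial peptide, by at least 13.6-fold. In the chemokine list 5 of 26 rose (11; median 1.79, adjusted p = 1.99e-07), with Ccl2 at 4.43 ± 0.79 and Cxcl5 at least 8.70-fold, and in the matrix list 5 of 24 (15; median 2.32, adjusted p = 1.93e-10), with Col5a2 at 4.09 ± 0.75. Of 14 NK, 16 B cell, 18 type I interferon and 22 p53 markers, 0, 0, 0 and 2 passed, with medians of 1.69, 0.83, 1.25 and 0.57 (adjusted p = 0.00263, 0.0335, 5.12e-04 and 0.0251); the NK median was 0.86 with floored values. Antigen presentation had a median of 0.43 (adjusted p = 0.0377), with 2 of 23 rising. T cell markers did not pass (median 0.86, adjusted p = 0.181), though they did with floored values (0.81, adjusted p = 0.0149). The lists of this paragraph gave adjusted p = 0.319 to adjusted p = 0.598 with an estimated correlation.

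Elovl3, measured on 1 of 2 tumour arrays, fell by 10.86 ± 0.94, Hsd3b5, a male-biased steroid enzyme, by 8.45 ± 0.69, and Mup6 fell by 8.32 ± 0.94, Mup5 fell by 8.25 ± 0.63 and Mup3 fell by 7.21 ± 0.79. Of 15 male-biased genes 8 fell (11 adjusted over the list alone; median -2.69, adjusted p = 1.19e-11), and of 27 cytochrome P450 enzymes 6 fell (16; median -1.83, adjusted p = 1.42e-11), Cyp2c54 by 6.82 ± 0.81 and Cyp2c37 by 5.31 ± 0.58. In the bile acid list 5 of 16 fell (9; median -1.81, adjusted p = 3.40e-04), with Cyp7b1 at -5.19 ± 0.76 and Cyp8b1 at -4.43 ± 0.87. In the urea cycle list 3 of 19 fell (4; median -1.32, adjusted p = 1.30e-06), with Hal, of histidine breakdown, at -3.32 ± 0.63 and Otc at -3.08 ± 0.53, and in the PPAR-alpha list 3 of 21 (5; median -0.88, adjusted p = 1.22e-04), with Cyp4a12a at -4.72 ± 0.60. Hepatocyte secreted genes (1 of 22 fell), gluconeogenesis (1 of 11), tyrosine catabolism (0 of 8) and lipogenesis (0 of 24) had medians of -1.46, -1.45, -1.37 and -1.02 (adjusted p = 1.39e-09, 5.66e-05, 0.00133 and 0.00232). With an estimated correlation these lists gave adjusted p = 0.319 to adjusted p = 0.638. Among lists that did not pass, NRF2 targets had a median of -0.11 but a mean of 0.55 (2 of 24 rose), the unfolded protein list a median of -0.59 and a mean of 0.22, and the acute phase list -0.38 and 0.19; the serine synthesis genes Psat1 and Phgdh rose by 4.97 ± 0.61 and 4.05 ± 0.61, Lcn2, a neutrophil and acute phase lipocalin, by 7.87 ± 0.86, while Alas2, of heme synthesis in red cells, fell by 4.41 ± 0.76. Slc1a2 differed by -1.89 ± 0.61 and Gsta1 by -0.17 without passing, and Krt76 and Lypd6b were not well above background on any of these arrays. The endothelial and female-biased lists also had means (0.16 and 1.37) opposite in sign to their medians (-0.23 and -0.28).

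Healthy liver was 1 array, assumed to vary like the other groups, and lay on slide 1 only. With slide as a block 2544 genes passed, the erythroid list passed as lower (median -1.18, adjusted p = 0.0168) and antigen presentation did not (adjusted p = 0.0767). The count was 500 without tumour replicate 2, 2134 without inflamed FCR replicate 1 and 2370 without inflamed FCR replicate 2, arrays that enter only through the shared spread; the other settings gave from 0 (floored values) to 781. The share of rises among the calls, 77.6%, was 59.3% with normexp and 67.0% with scaling on the array median.

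Inflamed FCR liver was set against normal FCR liver to describe the same withdrawal in mice without lymphocytes. Syt13, a synaptotagmin, rose by at least 595-fold (n = 2 and 1; limma, adjusted p = 0.00263), Sult2a6, a sulfotransferase, by at least 693-fold, Slc7a11 by at least 488-fold, Krt20 by at least 323-fold and Lypd6b by at least 142-fold. Oncofetal genes rose here too, 8 of 20 (17 adjusted over the list alone; median 3.12, camera adjusted p = 1.62e-19), with Igf2 at 8.38 ± 0.65, Ly6d at 7.57 ± 0.62, Afp at 6.27 ± 0.62 and Gpc3 at 5.84 ± 0.61. Of 24 NRF2 targets 6 rose (11; median 1.19, adjusted p = 1.85e-09): G6pdx by 4.54 ± 0.58, Cbr3 by 4.35 ± 0.84 and Srxn1, a sulfiredoxin, by 3.70 ± 0.54. Of 22 p53 targets 4 rose (9; median 1.15, adjusted p = 1.63e-06): the cell cycle inhibitor Cdkn1a by 4.56 ± 0.84, Phlda3 by 4.82 ± 0.68, Ddit4l by 5.14 ± 0.71 and Eda2r by 4.53 ± 0.76. With an estimated correlation the oncofetal and NRF2 lists had adjusted p = 0.370 and the p53 list adjusted p = 0.373.

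In all, 239 genes rose and 31 fell among 15381. Of 30 cell cycle genes 5 rose (19 adjusted over the list alone; median 2.82, adjusted p = 2.25e-15), with Ccnb1 at least 20.2-fold and Cdc20 at 3.56 ± 0.59. Of 15 neutrophil markers 5 rose (10; median 4.02, adjusted p = 1.96e-09), with Retnlg at 5.68 ± 0.76, S100a8 at 5.36 ± 0.97 and Mmp8, a neutrophil collagenase, at least 16.8-fold. Of 22 macrophage markers 2 rose (7; median 1.74, adjusted p = 1.44e-05), Gpnmb at least 48.6-fold and Cd14 by 4.43 ± 0.58, and of 26 lymphotoxin and chemokine genes 2 rose (10; median 1.63, adjusted p = 7.23e-08), Ptgs2 at least 23.2-fold and Cxcl2 at least 12.8-fold. The matrix, type I interferon and antigen presentation lists had no member that passed and medians of 1.45, 1.10 and 0.69 (adjusted p = 3.99e-05, 3.43e-04 and 0.0364). The T, B and NK lists did not pass (adjusted p = 0.992, 0.398 and 0.0533), though 1 NK list member, Eomes, rose at least 29.1-fold. Cpa3 was at least 1.38-fold higher and Mcpt4 differed by 0.72 ± 1.09, both without passing, Krt5 rose by 5.07 ± 0.66, Krt76 by at least 50.5-fold and Wdr64 by at least 29.1-fold, and Gsta1 differed by 2.09 without passing. With an estimated correlation the called lists had adjusted p = 0.370 to adjusted p = 0.431.

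Other genes fell in FCR liver. The change was -7.93 ± 0.69 for Hsd3b5, -6.70 ± 0.94 for Elovl3, -5.26 ± 0.93 for the lectin receptor Clec2h (measured on 1 of 2 inflamed arrays), -5.18 ± 0.62 for Hsd3b4, -4.65 ± 0.92 for the ferritin receptor Scara5 and -4.62 ± 0.61 for Slc1a2. Of 27 cytochrome P450 enzymes 3 fell (7 adjusted over the list alone; median -1.29, adjusted p = 1.34e-06), Cyp2c54 by 4.17 ± 0.81 and the pericentral Cyp2e1 by 2.80 ± 0.56. Of 16 Wnt targets and pericentral genes 2 fell (4; median -1.01, adjusted p = 1.80e-04), and of 15 male-biased genes 2 fell (8; median -1.48, adjusted p = 1.29e-09). Hepatocyte secreted, urea cycle, gluconeogenesis, tyrosine, bile acid, lipogenesis and acute phase lists had medians of -1.23, -1.30, -1.20, -1.17, -1.63, -0.76 and -0.75 (adjusted p = 5.24e-09, 1.02e-06, 3.00e-05, 9.64e-04, 0.00107, 0.00922 and 0.0302), though 1 acute phase gene rose. These lists had adjusted p = 0.370 to adjusted p = 0.681 with an estimated correlation, and with floored values the lipogenesis and acute phase lists did not pass (adjusted p = 0.0791 and 0.0805). In the PPAR-alpha list, which did not pass, 1 of 21 genes rose and 1 fell; Pdk4, a brake on glucose oxidation, rose by 4.44 ± 0.80. Of the lists that did not pass, the T cell, endothelial, erythroid and immediate early lists had medians of -0.08, -0.16, -0.18 and -0.01 and means of 0.18, 0.36, 0.20 and 0.33. Normal FCR liver was 1 array on slide 1. With slide as a block 1909 genes passed, the NK list passed (adjusted p = 0.0484) and antigen presentation did not (adjusted p = 0.135); within slide 1 the lipogenesis median was -1.64 and the neutrophil median 2.67. The count was 513 without tumour replicate 1, 458 without tumour replicate 2, 487 without inflamed FCR replicate 1 and 1807 without inflamed FCR replicate 2, and from 0 (floored values) to 364 in the other settings; rises were 88.5% of the calls, and 68.7% with normexp.

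Both genotypes shared much of this response. Of the genes tested, 167 rose in both, against 9.39 from independent lists of these sizes, and 25 fell in both, against 0.351; none passed in opposite directions, against 1.22 and 2.70. The 2 comparisons share no array, but they share each gene's estimate of the spread. A gene with a small estimate passes more readily in both. In both, the continuous NTBC array lay on slide 1 and replicate 2 of the other group on slide 2. A slide effect would thus enter both alike. Independent lists allow neither for that nor for the shared spread. Of 778 genes called in Fah, 98.8% had the same sign in FCR, and of 270 called in FCR 98.1% had the same sign in Fah. Within slide 1 the changes from continuous NTBC to off correlated across 15381 genes between genotypes (r = 0.663, rho 0.609; genes are not independent replicates).

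**Figure D3:**
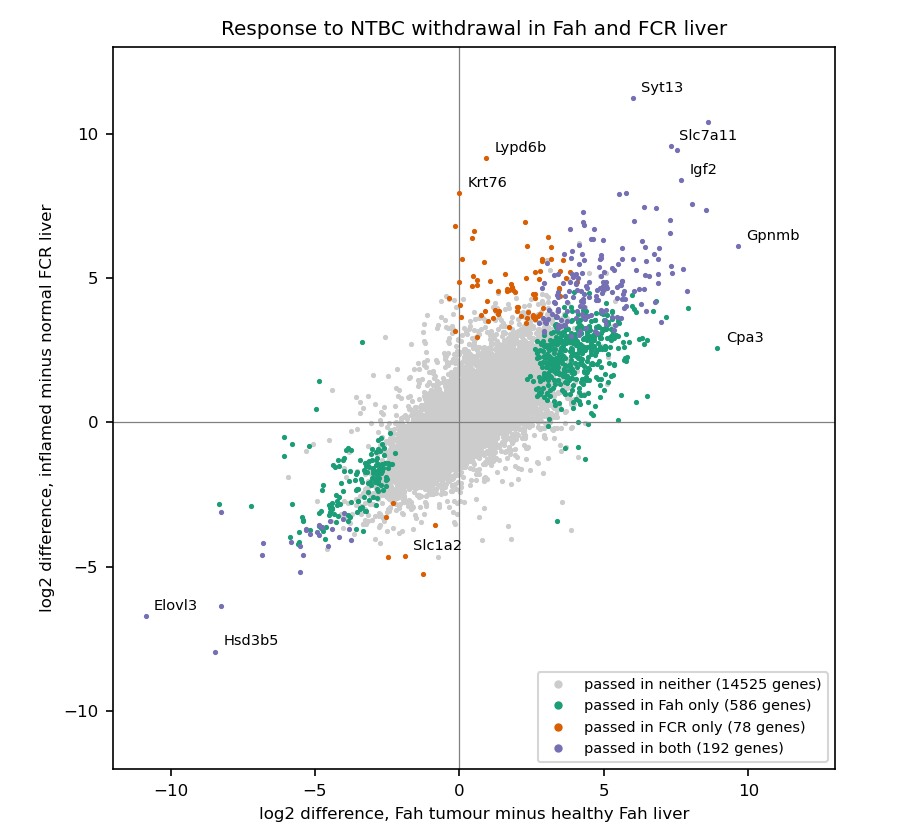
Log2 difference of each tested gene between tumour and healthy Fah liver (horizontal) and between inflamed and normal FCR liver (vertical), 1 point per gene, coloured by where it passed limma's test. Of the genes that passed in both, 167 rose in both and 25 fell in both; Lypd6b and Krt76 rose in FCR and were not well above background on any Fah array, and their difference of responses did not pass.

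Whether the response differed between Fah and FCR was tested as an interaction. No gene passed: limma called 0 of 15381, with 332 at an unadjusted p under 0.05 and a smallest adjusted p of 0.796. The Fah response ends in tumour and the FCR response in inflamed liver, so a difference need not come from genotype alone. The rule for named genes gave Lypd6b, Krt76, Wdr64, Nsun3 and Tex19.1 with a negative difference (Fah response minus FCR response) and Cd200r3, Myom2, a sarcomere protein, Cpa3, Slamf7 and Acvr1b with a positive one, none of which passed. Each was not well above background on the healthy Fah array, the normal FCR array or both, so no size of these differences is given. As a group, NRF2 targets had a median difference of -1.34, with all 24 members negative and 0 passing (camera, adjusted p = 5.28e-16); the list was higher after withdrawal in FCR (median 1.19) and was not called in Fah (-0.11). G6pdx differed by -2.89 ± 0.81 and Gclc, of glutathione synthesis, by -2.60 ± 0.78. The cell cycle list, called as higher in both genotypes, had a median difference of 1.51 (adjusted p = 1.15e-14; 0 of 30 passed). The Wnt and pericentral list had 1.27 (adjusted p = 1.27e-07; 0 of 16 passed, Slc1a2 2.73 ± 0.86): it was called as lower in FCR (median -1.01) and was not called in Fah (0.67, adjusted p = 0.844). Cdkn1a in the p53 list differed by -3.24 ± 1.19. With an estimated correlation the NRF2, cell cycle and Wnt lists had adjusted p = 0.554. With slide as a block 97 genes passed and 14 lists became 13, the bile acid list dropping out (adjusted p = 0.166). With floored values the acute phase list did not pass (adjusted p = 0.0589), while the T and B cell lists passed (adjusted p = 0.00756 and 0.0019). Without tumour replicate 1, 15 genes passed, without tumour replicate 2, 3, and without inflamed FCR replicate 2, 1.

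On continuous NTBC, 1 healthy Fah and 1 normal FCR array on the same slide were compared without a test. The values describe these 2 livers and cannot part a strain difference from one between single livers; percentiles among random lists carry the same limit. Of 14057 genes, 414 were over 2-fold higher in Fah and 688 in FCR; with normexp these were 136 and 216. Among genes not well above background on the other array, Zfp874a was at least 121-fold, Krtap9-3 at least 33.7-fold, Disp2 at least 20.2-fold, Qrfpr at least 17.7-fold and Camta1 at least 12.8-fold higher in Fah. In FCR, Myom2 was at least 301-fold, Dct at least 88.2-fold, Ifi202b at least 53.7-fold, Acvr1b at least 15.8-fold and Ifi44l at least 14.4-fold higher. The NK and B cell lists, with 7 and 13 members, lay higher in Fah, with medians of 1.51 and 1.07. These lay above all 10000 random lists of matched expression (percentile 100). Genes were compared if well above background on either array, so members can enter through the array where they are high. Such a difference rests partly on background, the random lists were not matched on detection, and no floored median was taken. The type I interferon list lay higher in FCR, with a Fah minus FCR median of -1.32 and 12 of 18 members over 2-fold, below all random lists (percentile 0). The T cell median of 0.25 lay at percentile 98.4. Other lists had smaller medians near either end of the random lists: higher on the Fah array were the P450 list (0.40, percentile 100), the urea cycle list (0.21, 99.99), hepatocyte secreted genes (0.16, 99.9), lipogenesis (0.14, 99.8) and PPAR-alpha targets (0.11, 99.3). Lower on the Fah array were the acute phase (-0.32, 0.06), chemokines (-0.34, 0.43), immediate early genes (-0.35, 0.62) and NRF2 targets (-0.25, 0.63). Each list not given here lay between percentiles 2.59 and 97.3.

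At off (slide 1) and at 2xoff/on (slide 2), which share no array, the tumour minus inflamed differences correlated across 15381 genes with r = 0.470 and rho 0.374. Of 1521 genes over 2-fold in both, 86.7% had the same sign; genes are not independent replicates, and no p-value is given.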

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

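The tests of every probe on its own and with floored values were chosen after the results were seen.

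The withdrawal response of 14 lists differed between Fah and FCR by the interaction test with camera's preset correlation. Differences are the Fah minus the FCR response, as list medians. Lists with a positive median in FCR and a lower one in Fah were NRF2 targets (-1.34; 1.19 in FCR and -0.11, not called, in Fah) and p53 targets (-0.68; 1.15 and 0.57). Lists with a negative median in both, further down in Fah, were cytochrome P450 enzymes (-0.89; -1.29 in FCR and -1.83 in Fah), male-biased genes (-0.72; -1.48 and -2.69), bile acid genes (-0.98; -1.63 and -1.81) and PPAR-alpha targets (-0.96; -0.32, not called, and -0.88). Erythroid markers (-1.15) and the unfolded protein list (-0.57) were called in neither genotype. Lists called as higher in both, with the larger median in Fah, were the cell cycle (1.51), matrix genes (1.02), macrophage markers (1.08) and oncofetal genes (0.88). Wnt targets and pericentral genes (1.27; -1.01 in FCR and 0.67 in Fah) and the acute phase (0.37; -0.75 and -0.38) were called as lower in FCR and were not called in Fah. None of the 14 passed camera with an estimated correlation, where the smallest adjusted p was 0.554. That form found a raised list in 0 of 5 simulated draws for this difference. Within slide 1 macrophage markers had the other sign (-0.26), and the medians were -0.35 for bile acid genes, -0.50 for erythroid markers, -1.17 for p53 targets and 1.00 for the acute phase.

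Probes without a gene name stand outside the gene comparisons. Tested one by one among 7825 such probes, 13 passed in tumour against inflamed FCR liver (10 higher, 3 lower), 43 in Fah tumour against healthy liver (24 higher, 19 lower) and 5 in inflamed against normal FCR liver (4 higher, 1 lower).

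The lower NRF2 list in tumour than in inflamed FCR liver was weighed against technical explanations. Inflamed FCR replicate 1 stands apart from the other arrays, but within slide 2, which lacks it, the list's median was -1.61. This was below random lists with both tails left out (-0.47 to -0.05), and 24 of 24 members were lower on both slides. Values near background lifted by the scaling could touch little of the list, since 1 of 24 members lay under the floor on any array. For the same reason flooring could hardly move the list's median, which was -1.62, and is no separate evidence. These values argue against both technical explanations. A difference between Fah tumour and inflamed FCR liver may remain as a hypothesis found and tested on the same arrays. Differences in the amount of tumour or of injury between the livers stay open and were not tested.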

How the results depend on the processing

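Flooring and the test of every probe were chosen after seeing the data. Replicate numbers were given in sample order and coincide with slide, so that slide as a block also pairs arrays by number. Of 178 gene results under the alternatives, 2499 values were obtained: 2035 kept direction and side of the threshold, 244 no longer passed, 204 newly passed and 16 were counted as reversed. Of these 16, 2 floored values were exactly 0 and so have no direction. Dim genes limit the precision, since 60.5% to 74.5% of spots were well above background. Normexp used the median signal.

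Counts of genes that moved over 1.5 times are given in the order design text, tumour against inflamed, Fah, FCR and difference, where they apply; the cause was not tested unless stated. Slide as a block gave 51, 984, 2544, 1909 and 97, with 1 residual degree of freedom, so that p rests on the spread shared by genes. Normexp gave 2, 190 and 1 (design text, inflamed, difference) and 352 genes over 2-fold on continuous NTBC against 1102. Quantile normalization gave 12, 472 and 119, no filter 11 (inflamed) and 159 (FCR), the strict filter 4, 430 and 138, and the authors' values 4, 263 and 54. The array median gave 1 (design text) and 80 (inflamed), and eBayes without trend 49 (inflamed). Floored values gave 0, 0 and 0 (inflamed, Fah, FCR) by limma, with smallest adjusted p of 0.194, 0.111 and 0.145 and 1405, 2525 and 1830 genes at an unadjusted p under 0.05; 359 tested genes were left without spread, and the prior degrees of freedom were 1.43 against 6.81. Every probe on its own gave 363 (Fah) and 73 (FCR). For the design text, all 3 FCR arrays gave 1 and both inflamed FCR arrays 35. Leaving out 1 array gave 0 to 2265, 56 to 799, 500 to 2370, 458 to 1807 and 0 to 15. An estimated correlation and fry's one-way form passed 0 lists in every comparison, against 24, 15, 20, 20 and 14, while fry in either direction passed 3, 9, 22, 15 and 0; unadjusted, 2, 2, 1, 1 and 1 lists passed with an estimated correlation and 7, 8, 9, 8 and 1 with fry one way, and fgsea passed 23, 16, 21, 20 and 12.

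The reversed values, none of a gene that passed in its comparison, follow, with the range over arrays left out where 1 of them reversed. For the design text, Afp was -0.12 without FCR normal replicate 1 (-0.12 to 5.65) and -0.62 against both inflamed FCR arrays, where Scd1 was 0.31. In tumour against inflamed FCR liver, Afp was 0.10 with quantile normalization and Cd3e was 0.042 without inflamed replicate 2 (-0.70 to 0.042). In Fah, Lypd6b was -0.85 with normexp and 0 when floored, Krt76 0.69 with quantile normalization, 0.56 without tumour replicate 1 (-0.57 to 0.56) and 0 when floored, and Gsta1 0.57 with quantile normalization, 0.18 with the slide block, 0.61 with the authors' values and 0.095 without tumour replicate 2 (-0.44 to 0.095). In FCR, Cpa3 was -0.087 with normexp and Mcpt4 -0.14 with the slide block.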

Other observations

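The tests at sizes of 1 and 3 on the log2 scale and the brightness test below were chosen after the results were seen, as were the genes named in the next paragraph.

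Genes that differed between Fah and FCR arrays by over 4-fold in the same direction at all 3 regimens numbered 50, with 21 higher in Fah and 29 in FCR. Beside Ifi202b, Zfp874a, Il2rg and Jchain they held Rab6b, Ifi44l, the T cell GTPase Gimap3, the renin genes Ren1 and Ren2, and Cyp2g1.

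Of these genes 14 had a second probe, and their other probes differed by a median of 2.29 in the gene's direction. This argues against a sequence variant under the probe for the genes whose other probe shared the direction. For 3 genes (Arsk, Clmp and Nlrp12) the other probe went the other way, so a variant stays open for them. It also stays open for the 36 genes with no other probe. Chromosome segments that differ between the strains cannot be told apart from other causes: 6% of the 50 genes had another such gene among their 10 nearest, within the range of 1000 random sets (0 to 18), which met the bound set beforehand for excluding segments. That bound depended on the size asked of a difference, which had not been fixed: with 165 genes at a size of 1 the share was 23.6%, above the highest random set at 22.4%, and with 20 genes at a size of 3 it was 0%. Among the 100 genes nearest to Rag2, Il2rg and Fah there were 0, 1 and 0 such genes, the 1 being Il2rg itself. By the positions used, the renin genes Ren1 and Ren2, both on chromosome 1 and higher in FCR, were not counted as neighbours. The shares above depend on those positions. Of the 21 genes lower in FCR 23.8% were in the T, B or NK lists, so that missing lymphocytes may account for a part of them. Membership of these short lists is a low count. Il2rg, which FCR mice lack by design, and the T cell GTPase Gimap3 are among the 21 and stand outside the lists. How many of the others come from lymphocytes was not tested.

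A candidate source of Cpa3 and Mcpt4 in the tumours is mast cells, as a hypothesis. Array brightness was not decided. Within slide 2 the lower of both differences was 7.21, but both genes were picked for large differences over the same arrays, so a small value was hardly possible. On slide 2 the tumour array was also the brighter, with a 75th percentile of 890 against 722. From 20 mast cell markers listed before the test, 12 measured ones not looked at before had a median difference of 1.81 between tumour and inflamed FCR liver, against -0.57 to 0.69 in random lists with both tails left out, and 11 of 12 were positive. Ms4a2, Mcpt1, Mrgprb1 and Cyp11a1 were well above background on only 2 arrays, neither of them healthy or normal liver. Such a marker can enter through the group where it is high, and its size rests partly on background. Mcpt2, above background on 0 arrays, was left out, and no floored median was taken. Within slide 1 the median was 1.60 with 8 of 12 positive, and within slide 2 it was 2.39 with 11 of 12. Of all markers only Cpa3 and Mcpt4 passed the test, and with regimen as a block neither did (limma, adjusted p = 0.232 and 0.212). That fit also takes in the continuous NTBC pair, so it does not ask the same question. In that pair Cpa3 was at -7.25 in Fah and -7.62 in FCR, and Mcpt4 at -3.72 and -4.42. Cma1, a mast cell chymase, differed by 5.0, Tpsb2, a tryptase, by 3.51, Fcer1a, of the IgE receptor, by 3.25 and the histidine decarboxylase Hdc by -0.87. Of the markers 7 were well above background on a healthy or normal liver array and 0 were in the other lists; no sort or gate is named in the labels.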
